A study of Mus musculus with 7 samples.

How the data were processed

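Messenger RNA of single mouse DCs was measured by SORT-seq, a plate form of the CEL-Seq2 method that reads the 3' ends of transcripts, on 7 plates of 384 wells each. Per the labels, cells of the draining lymph node had been depleted of cells bearing CD3 or CD19, and live migratory DCs without CD64 had been sorted 1 per well by SIRPα, XCR1 and Epcam. The deposited values are read counts per gene and well, 1 table per plate, made by the authors' sequencing provider without normalization. Although the chemistry carries molecular identifiers, the values were used as reads, since their median non-zero value in kept cells was 10 and 0 of them were not whole numbers. Reads are not independent molecules, so intervals and floors cover counting error only. The submitters' processing notes name STAR 2.7.3a, Seurat 3.2.2 and the human build hg38, whereas 32219 of the 32315 single gene identifiers in the tables matched the mouse annotation GENCODE M21, whose GRCm38 coordinates are given, counted from 1. Reads that the tables assign to several genes at once made up between 3.86% and 4.69% of a plate. Where all but 1 of the genes were predicted genes or microRNAs, the reads were counted for the named gene. Lilr4b, given below, came only from such shared reads. Other shared reads were kept under their joint names, and spike-in reads were left out of the gene totals.

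Wells were kept as cells with at least 500 genes detected and at most 25% of reads from mitochondrial genes. This kept 1710 cells and left out 978 wells, 84 of them over the mitochondrial limit. No column of per-well values was unused, and 0 pairs of plates had identical gene totals. As no label names the subset in a well, classes were rebuilt from the transcriptomes. Counts were scaled to 10000 per cell and log-transformed, 1500 variable genes seen in at least 30 cells were centred within each plate and clipped at 8, and 30 principal components were taken. Leiden clusters were drawn on a shared neighbour graph, with 20 neighbours and resolution 2 in a first pass of 18 clusters, of which 5 were set aside. A second pass on the remaining 1349 cells, with 40 neighbours and resolution 1, gave 4 clusters. Clusters were named by marker lists fixed before the data were examined, a marker counting when its mean was at least 1 CPM and at least 1.25 times that of the other clusters after adding 5 CPM, with at least 3 markers for a name. These clustering parameters were chosen after the clusters and their marker levels had been seen, and before any test between groups. Centring within plates removes differences of mean level between plates, so class shares are not read as biology. No doublet caller was run, as wells were sorted to hold single cells.

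The 361 cells set aside, 21.1% of the kept cells, were 300 of low depth, with a cluster median under 1 part in 3 of the plate's, 35 mast-like and 26 macrophage-like cells. Because the subsets were sorted into plates in set numbers, the shares of classes describe the plates only. LC-like cells made up 31.1% and 30.0% of kept cells on the 1-week plates, 17.6% and 19.3% on the 3-week plates, 19.6% and 30.3% on the 8-week plates and 29.7% on the OVA- plate. Low-depth cells made up 10.2%, 10.6%, 29.0%, 28.9%, 29.2%, 18.3% and 16.1% of the plates in the same order.

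For each class, reads were summed over the cells of a plate, at least 10 of them, and the plate was the replicate. The sums held 2.39 to 9.78 megareads for LC-like, 6.92 to 14.7 megareads for cDC2-like and 3.58 to 19.2 megareads for cDC1-like cells. Genes passing filterByExpr, 14402, 16821 and 14877 of them, were fitted with 1 mean per group by edgeR 4.0.16, with TMM scaling and the robust quasi-likelihood test, and p values were adjusted by the Benjamini-Hochberg method over all genes of a class at a threshold of 0.05. The 4 groups shared 1 estimate of the spread with 3 residual degrees of freedom, and the OVA- plate, alone in its group, was assumed to vary like the others. Comparisons were 8 weeks with 1 week and the mean of the OVA+ times with OVA-, as main ones, and 3 weeks with 1 week and 8 weeks with 3 weeks. A further fit with plate as a block tested whether the change from 1 to 8 weeks differed between LC-like and cDC2-like cells. CPM values of named genes and of list means use library sizes scaled by TMM, and CPM values of class markers use plain totals. Medians of lists are medians of fitted log2 differences, in which genes near 0 depend on the prior count, whereas list means are of log2(CPM + 1). Gene lists, 19 in all, were tested by camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2, again with an estimated correlation, and by fry. Intervals of shares are exact binomial intervals at 95% confidence.

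Genes were named by a rule fixed before the data were examined. Of the genes past the threshold with a mean of at least 20 CPM and no overlap between plates of the groups, the 5 largest rises and 5 largest falls were to be named in a main comparison and 3 of each in a secondary one, leaving out unnamed gene models, ribosomal, mitochondrial and spike-in names. To these were added up to 15 members of the fixed lists with the smallest p in a main comparison, without the ribosomal and mitochondrial lists. Where no gene passed, as in every comparison here, the 6 genes with the smallest p were named and said not to pass.

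The test was tried on simulated data with the measured library sizes and spread for 8 weeks against 1 week, 100 genes being changed 4-fold and 100 genes 16-fold. With the spread following the trend of all genes, it recovered 7%, 17% and 11% of the 4-fold and 45%, 64% and 58% of the 16-fold changes in LC-like, cDC2-like and cDC1-like cells, and 3.7%, 1.22% and 6.76% of its calls were false. When each gene kept its own spread, it recovered 1%, 28% and 14% of the 4-fold and 37%, 69% and 52% of the 16-fold changes, and 15.6%, 20.5% and 9.59% of the calls were false. The median biological coefficient of variation of genes with at least 20 CPM was 0.516, 0.376 and 0.447.

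Alternatives planned before the data were examined were DESeq2 1.42.0, edgeR without TMM, no filter on low counts, cells with at least 1000 genes (1595 cells), resolutions 0.5 and 2 for the shares of classes, classes by marker score, limma-trend on log2 of the mean CPM over cells with 1 CPM added, and leaving out each plate in turn. Others were added after the data had been seen and are named in the closing section. Classes by marker score put every kept cell in a class, also the cells set aside from the clusters. Without TMM, the median log2 difference of all genes moved by 0.236, 0.127, 0.109 and -0.138 in LC-like cells for 8 weeks against 1 week, 3 weeks against 1 week, 8 weeks against 3 weeks and OVA+ against OVA-. In the same order it moved by 0.127, 0.144, -0.017 and -0.0266 in cDC2-like and by 0.0942, -0.0178, 0.112 and -0.127 in cDC1-like cells. The 37 list calls were all shared in the same direction, but camera compares a list with the other genes, so such shifts could hardly change them. The distance between 2 plates was the median absolute log2 difference over genes of at least 20 CPM, over 100 draws of 15 cells per plate with a fixed seed, with all reads and with 20000 reads per cell. Further tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3.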

Results

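Single dendritic cells (DCs) were profiled from draining lymph nodes in a study of epicutaneous immunotherapy, in which allergic C57BL/6 mice received 8 weekly patches of ovalbumin (OVA), each worn for 48 hours. Migratory DCs had been sorted into plates of 384 wells by surface proteins, as Langerhans cells (LC), type 2 conventional DCs (cDC2) and type 1 conventional DCs (cDC1), and each of the 7 plates mixed the 3 subsets. OVA+ DCs had been taken at 1, 3 and 8 weeks, with 2 plates per time, and OVA- DCs of allergic mice, labelled T0, filled a single plate. The labels do not say what T0 means, whether plates of 1 time came from separate mice, or which well held which subset.

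At 1 week the plates held 30684761 and 32291141 gene reads and 334 and 330 kept cells, for replicates 1 and 2 in that order. The 3-week plates held 20190982 and 16184124 reads and only 131 and 83 kept cells, and spike-in RNA made up 95.7% and 98.7% of the reads of their median well. At 8 weeks there were 28885772 and 30885329 reads and 219 and 290 kept cells. The OVA- plate held 45628849 reads and 323 kept cells. Median gene reads per kept cell ranged from 82026 to 157190, and median genes per kept cell from 2293 on the OVA- plate to 3293 on the first 1-week plate.

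Grouping the 1710 kept cells by their transcriptomes gave 469 LC-like, 475 cDC2-like and 405 cDC1-like cells. Cd207, which encodes langerin, averaged 32.0 ± 29.8 counts-per-million (CPM; mean ± SD, n = 7 plates) in LC-like cells against 0.328 CPM in cDC2-like and 6.02 CPM in cDC1-like cells, and was highest in LC-like cells on 7 of 7 plates. Epcam, an adhesion molecule of Langerhans cells, averaged 29.7 ± 12.3 CPM in LC-like cells and was highest there on 6 plates. Sirpa, the gene of a protein used in the sort, averaged 103 ± 42.0 CPM in cDC2-like cells against 63.4 CPM in LC-like and 6.62 CPM in cDC1-like cells. Mgl2, a lectin of cDC2, averaged 2.97 ± 3.02 CPM in cDC2-like cells and was highest there on 4 plates. In cDC1-like cells, Irf8, a transcription factor needed for cDC1, averaged 3561 ± 1660 CPM against 1897 and 827 CPM in LC-like and cDC2-like cells and led on 7 plates. Xcr1, the chemokine receptor of cDC1, averaged 18.3 ± 34.8 CPM in cDC1-like cells and led on 4 plates, and Cadm1 was as high in LC-like cells, at 74.5 CPM, as in cDC1-like cells, at 73.5 CPM. Other listed markers went against the names. The cDC1 markers Naaa, Ppt1, Wdfy4, Itgae and Tlr3 averaged higher in cDC2-like than in cDC1-like cells, Naaa at 16.8 against 1.78 CPM. The LC marker Ltc4s averaged 170 CPM in cDC2-like and 127 CPM in LC-like cells. Csf1r, listed for cDC2, averaged 8.83 CPM in LC-like and 8.25 CPM in cDC2-like cells. The same lists had named the clusters, so these values are no independent check. The classes are thus approximate, and a class taken from each cell's marker scores matched the class by clustering in 52.0% of the named cells. Classes by marker score also took in the cells set aside. Results that ended or turned by marker score therefore rest on another set of cells as well.

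**Figure D1:**
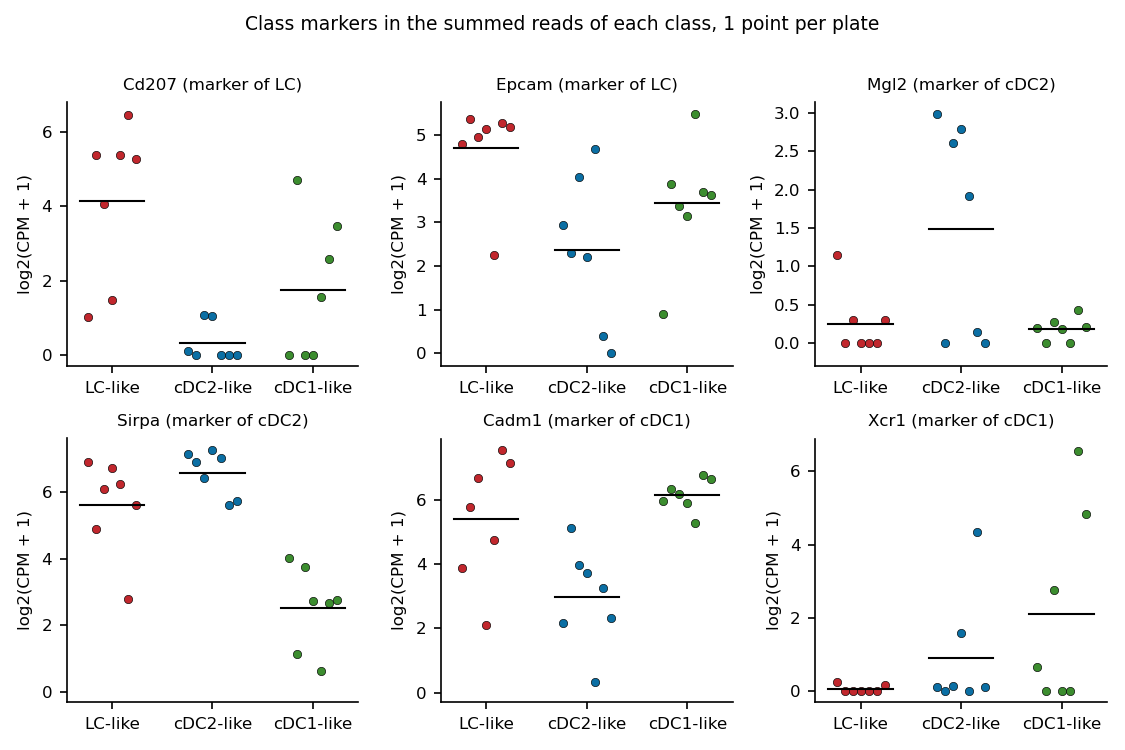
Levels of Cd207, Epcam, Mgl2, Sirpa, Cadm1 and Xcr1 in the 3 classes as log2(CPM + 1), with 1 point per plate and 7 points per class. Cd207 was highest in LC-like cells on 7 of 7 plates, whereas Xcr1 was highest in cDC1-like cells on 4.

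The LC-like class joined 2 clusters that were filled unequally by the plates. Cluster 2, with 275 cells, carried Cd207, Epcam, Lad1, Cldn1 and Mfge8. Cluster 3, with 194 cells, carried Epcam, Lad1 and Cldn1 but little Cd207, also carried 2 markers of each other class, and among its top genes were Ccl22, Cd86, Dll4, Gpr183 and Ccnd2. Only 3 plates held enough of its cells for the naming, and Epcam was higher on 2 of them. The cDC2 markers Sirpa and Irf4 averaged 113 and 137 CPM in cluster 3, against 98.1 and 82.7 CPM in the cDC2-like cluster. Mgl2 and Itgam were lower than in the cDC2-like cluster, and whether cluster 3 holds Langerhans cells is uncertain. Of the LC-like cells, cluster 3 held 92 of 104 (88.5%) and 74 of 99 (74.7%) on the 1-week plates and 6 of 23 (26.1%) and 4 of 16 (25%) on the 3-week plates. The shares were 10 of 43 (23.3%) and 4 of 88 (4.55%) on the 8-week plates and 4 of 96 (4.17%) on the OVA- plate. In LC-like cells Cd207 measured 1.02 and 1.78 CPM on the 1-week plates and between 15.7 and 87.0 CPM on the others. Every LC-like comparison with 1 week therefore sets a class made mostly of cluster 3 against one made mostly of cluster 2. The other classes were 1 cluster each, but their makeup differed as well when cells were clustered at resolution 2, a count made after the data had been seen. Of the cDC1-like cells, 65 of 82 and 57 of 81 on the 1-week plates then fell in 1 cluster, against 11 of 44 and 1 of 69 on the 8-week plates and 3 of 86 on the OVA- plate. Of the cDC2-like cells, 48 of 105 and 42 of 109 fell in another, against 13 of 56 and 2 of 69 at 8 weeks and 3 of 75 on the OVA- plate. No comparison was made within these smaller clusters, so changes given below for cDC2-like and cDC1-like cells include such differences of makeup.

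**Figure D2:**
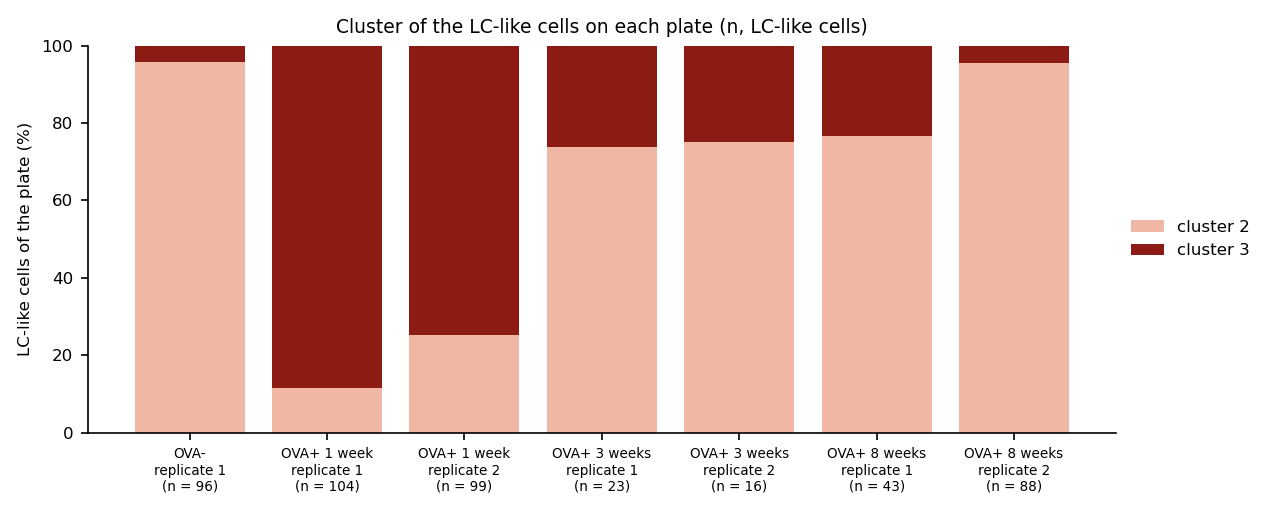
Percent of the LC-like cells of each plate in cluster 2 and cluster 3, as stacked bars from 0 to 100. Cluster 3 made up 88.5% and 74.7% on the 1-week plates and at most 26.1% on each other plate.

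Genes were tested within each class with the plate as the replicate. By edgeR, 0 genes passed a false discovery rate (FDR) of 0.05 in each of the 12 class comparisons, with between 594 and 1516 genes at an unadjusted p of 0.05 or less. If no gene differed, about 720, 841 and 744 genes would reach that p in LC-like, cDC2-like and cDC1-like cells. In cDC1-like cells the counts for both main comparisons lay below this number. DESeq2 called between 18 and 372 genes per comparison, and edgeR without its filter on low counts called between 39 and 437. The limma fit on mean CPM over cells called 147 genes for OVA+ against OVA- in cDC2-like cells, 114 in cDC1-like cells and 0 elsewhere. Of 228 tests of gene lists fixed before the data were examined, 37 passed an adjusted p of 0.05 by camera with its preset correlation between genes. With a correlation estimated from the plates 0 of these calls held, and 7 held by fry, so every call of a list given here depends on the form of the test. Summed over all lists and comparisons, members were higher 58 times and lower 53 times when adjusted over the list alone. In this sum and in those by class below, a gene in several lists counts once per list. The sum over comparisons also counts it once per comparison, and no adjustment was made across lists. Gene values are mean CPM ± SD over n = 2 plates per time unless stated otherwise, and genes named did not pass the test over all genes.

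The comparison of 8 weeks with 1 week asked how OVA+ DCs changed over the course of patches. In LC-like cells, type I interferon response genes, cholesterol synthesis enzymes, regulatory molecules and glycolysis genes lay lower at 8 weeks, and MHC class II genes lay higher. Tcf7l2, a transcription factor of the Wnt pathway (ENSMUSG00000024985, chromosome 19, 55741820 to 55933654, GRCm38), measured 17.2 ± 7.3 CPM at 1 week and 239 ± 32.0 CPM at 8 weeks, a log2 difference of 3.79 (SE 0.459, FDR 0.177). Sox4, a transcription factor, measured 13.04 ± 2.9 and 156 ± 0.127 CPM, a log2 difference of 3.58 (SE 0.464, FDR 0.177). Tnfrsf9, a costimulatory receptor, measured 819 ± 92.2 CPM at 1 week and 187 ± 0.495 CPM at 8 weeks, a log2 difference of -2.13 (SE 0.311, FDR 0.177). The antisense transcript Gm13546 had lower values at 8 weeks, 140 against 773 CPM, and reads shared by Evi2 and Evi2a had higher ones, 117 against 2.01 CPM. Cdcp1 measured 0.195 CPM at 1 week and 36.0 CPM at 8 weeks, too few reads at 1 week for a stable ratio. Among the members of the lists, Il1b, a proinflammatory cytokine, measured 256 ± 5.44 and 12.5 ± 11.9 CPM, and Nfkb1 1991 ± 319 and 609 ± 194 CPM. Ccr7, the receptor that guides DCs to lymph nodes, measured 1383 ± 163 and 677 ± 47.9 CPM. Icosl, the ligand of the costimulatory receptor ICOS, measured 3.51 ± 2.02 CPM at 1 week and 248 ± 231 CPM at 8 weeks, where the 2 plates lay far apart.

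As sets in LC-like cells at 8 weeks, 16 of 21 measured members of the type I interferon response list were lower, with a median log2 difference of -1.81 (adjusted p = 8.63e-06, and adjusted p = 0.429 with an estimated correlation). Stat1 measured 384 CPM at 1 week and 109 CPM at 8 weeks, and Cxcl10 26.6 and 0 CPM, whereas Mx1 went the other way, from 19.4 ± 4.99 to 289 ± 227 CPM. In cholesterol synthesis 16 of 17 members were lower, with a median of -0.84 (adjusted p = 0.00355, and adjusted p = 0.429 with an estimated correlation). Of the regulatory and tolerogenic list 18 of 23 members were lower, with a median of -0.59 (adjusted p = 0.0120, and adjusted p = 0.717 with an estimated correlation), among them Cd200, at 440 and 78.8 CPM. Glycolysis and hypoxia genes were lower for 13 of 18 members, with a median of -0.76 (adjusted p = 0.0147, and adjusted p = 0.708 with an estimated correlation). MHC class II presentation was higher for 12 of 15 members, with a median of 1.07 (adjusted p = 0.033, and adjusted p = 0.429 with an estimated correlation), H2-Eb1 measuring 541 and 2316 CPM. Ribosomal protein genes were higher for 64 of 84 members, by a median of 0.29 (adjusted p = 0.0370, and adjusted p = 0.717 with an estimated correlation). By edgeR 0 genes passed, with 826 of 14402 at an unadjusted p of 0.05 or less, while DESeq2 called 116 higher and 83 lower and limma called 0. Adjusted over the list alone, 7 member genes were higher and 9 lower. Scaling by total reads in place of TMM moved the median of all genes by 0.236 on the log2 scale, close to the median of the ribosomal list. It left every list call in place, but camera compares a list with the other genes, so a shift of all genes could hardly change a call. Without single plates the calls ended for cholesterol synthesis (without 8-week replicate 1, adjusted p = 0.0618), for the regulatory list (without 1-week or 8-week replicate 2, up to 0.347) and for glycolysis (without 8-week replicate 2 or the OVA- plate, up to 0.42). They also ended for MHC class II (without either 3-week plate, 8-week replicate 1 or 1-week replicate 2, up to 0.200) and for the ribosomal list (without 1-week replicate 1 or either 8-week plate, up to 0.587), and the interferon call stayed whichever plate was left out, with adjusted p of at most 0.00584. In the cells of cluster 2 alone, only the call of the regulatory list stayed (adjusted p = 0.00922). There the interferon, glycolysis, cholesterol and MHC class II lists had adjusted p of 0.175, 0.175, 0.0563 and 0.348, and the ribosomal list went the other way (adjusted p = 0.539). Classes by marker score ended the MHC class II and ribosomal calls (adjusted p = 0.810 and 0.131). Genes of at least 20 CPM ended the interferon and glycolysis calls (0.111 and 0.119). Leaving out both 3-week plates ended the MHC class II call (0.0770).

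In cDC2-like cells, the chemokine gene Ccl22, the ligand genes Cd80, Cd86 and Pdcd1lg2 and the cytokine signalling inhibitor Socs3 had lower values at 8 weeks than at 1 week, over a class whose makeup differed between these plates. Gcnt2, a glycosyltransferase (ENSMUSG00000021360, chromosome 13, 40859754 to 40960892, GRCm38), measured 55.8 ± 0.41 CPM at 1 week and 3.60 ± 0.714 CPM at 8 weeks, a log2 difference of -3.95 (SE 0.554, FDR 0.516). Tead2, a transcription factor of the Hippo pathway, measured 10.6 ± 0.813 and 74.1 ± 14.4 CPM, a log2 difference of 2.80 (SE 0.413, FDR 0.516), and Pbx1, a homeobox transcription factor, 74.8 ± 9.09 and 272 ± 34.6 CPM. Glipr2 and Ttyh3 had lower values, 175 against 535 CPM and 343 against 982 CPM, and 2610035D17Rik higher ones, 45.4 against 4.89 CPM. Ccl22, a chemokine that attracts Ccr4-bearing T cells, measured 6804 ± 263 CPM at 1 week and 2339 ± 861 CPM at 8 weeks, a log2 difference of -1.54 (SE 0.302, FDR 0.516). Socs3, an inhibitor of cytokine signalling, measured 42.6 ± 4.17 and 4.74 ± 0.368 CPM, and Cish, of the same family, 57.8 ± 7.42 and 5.98 ± 2.72 CPM. The costimulatory ligands Cd86 and Cd80 measured 470 ± 88.3 and 125 ± 26.7 CPM at 1 week and 108 ± 94.4 and 50.9 ± 7.18 CPM at 8 weeks. Pdcd1lg2, which encodes the inhibitory ligand PD-L2, measured 1074 ± 122 and 226 ± 220 CPM, a log2 difference of -2.25 (SE 0.634, FDR 0.673). Of the 15 list members with the smallest p, 13 had lower values and 2, Slco5a1 and Icosl, higher ones.

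The regulatory and tolerogenic list lay lower in these cells for 18 of 23 members, with a median of -0.62 (adjusted p = 0.0128, and adjusted p = 0.487 with an estimated correlation). Ribosomal protein genes lay higher for 71 of 85 members, with a median of 0.37 (adjusted p = 0.000429, and adjusted p = 0.704 with an estimated correlation). The regulatory call ended without either 1-week plate or 8-week replicate 2, up to an adjusted p of 0.0781, and the ribosomal call without 1-week replicate 1 or 8-week replicate 2, up to 0.115, as well as by marker score (0.666). The edgeR test called 0 genes, with 922 of 16821 at an unadjusted p of 0.05 or less, while DESeq2 called 76 higher and 91 lower and limma called 0. When adjusted over the list alone, 2 member genes were higher and 9 lower.

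In the cDC1-like class, whose makeup also differed between the plates, MHC class II genes had higher values at 8 weeks than at 1 week. H2-Eb1, a class II beta chain, measured 1463 ± 54.7 CPM at 1 week and 3954 ± 737 CPM at 8 weeks, a log2 difference of 1.43 (SE 0.28, FDR 0.819). H2-Eb2 measured 28.4 ± 13.4 and 125 ± 11.1 CPM, and Cd74, the invariant chain, 1984 ± 0.651 and 3726 ± 154 CPM. Icosl (ENSMUSG00000000732, chromosome 10, 78069302 to 78083913, GRCm38) measured 11.5 ± 2.07 CPM at 1 week and 248 ± 188 CPM at 8 weeks, a log2 difference of 4.42 (SE 0.584, FDR 0.158). Gfpt2, an enzyme of hexosamine synthesis, measured 1.90 ± 1.08 and 66.8 ± 26.2 CPM, a log2 difference of 5.13 (SE 0.775, FDR 0.321). The sialyltransferase gene St8sia6 had higher values at 8 weeks, 47.7 against 1.32 CPM, and B3gnt5, a glycosyltransferase gene, lower ones, 12.4 against 87.0 CPM. Gcnt2 measured 108 ± 0.651 CPM at 1 week and 0.12 CPM at 8 weeks, near the floor of detection, as also at 3 weeks and on the OVA- plate. Of the 15 list members with the smallest p, 10 had higher values and 5 lower ones, the latter Il1rn, Stat1, Id2, Lamp1 and Tgfbi, although Tgfbi turned to a log2 difference of 0.19 by marker score.

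As a set, MHC class II presentation lay higher for 11 of 15 members, with a median of 0.80 (adjusted p = 0.0288, and adjusted p = 0.771 with an estimated correlation). Cholesterol synthesis lay higher for 13 of 16 members, with a median of 0.58 (adjusted p = 0.0288, and adjusted p = 0.771 with an estimated correlation). Leaving out any of the 1-week or 8-week plates ended the MHC class II call, up to an adjusted p of 0.180, and leaving out 1-week or 8-week replicate 2 ended the cholesterol call, up to 0.361. With classes by marker score the MHC class II list was not called (adjusted p = 0.196), and the cholesterol list went the other way (adjusted p = 0.281). By edgeR 0 genes passed, with 594 of 14877 at an unadjusted p of 0.05 or less, while DESeq2 called 41 higher and 40 lower and limma called 0. Without 3-week replicate 1, 3-week replicate 2 or 8-week replicate 1, edgeR called 3 genes each time. These were Gcnt2, Got1 and Scin, all lower, without either 3-week plate, and Flrt3 and Pdcd1lg2, lower, and Icosl, higher, without 8-week replicate 1. Got1, Scin, Flrt3 and Pdcd1lg2 are named here after their values were seen. Adjusted over the list alone, 5 member genes were higher and 1 lower.

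**Figure D3:**
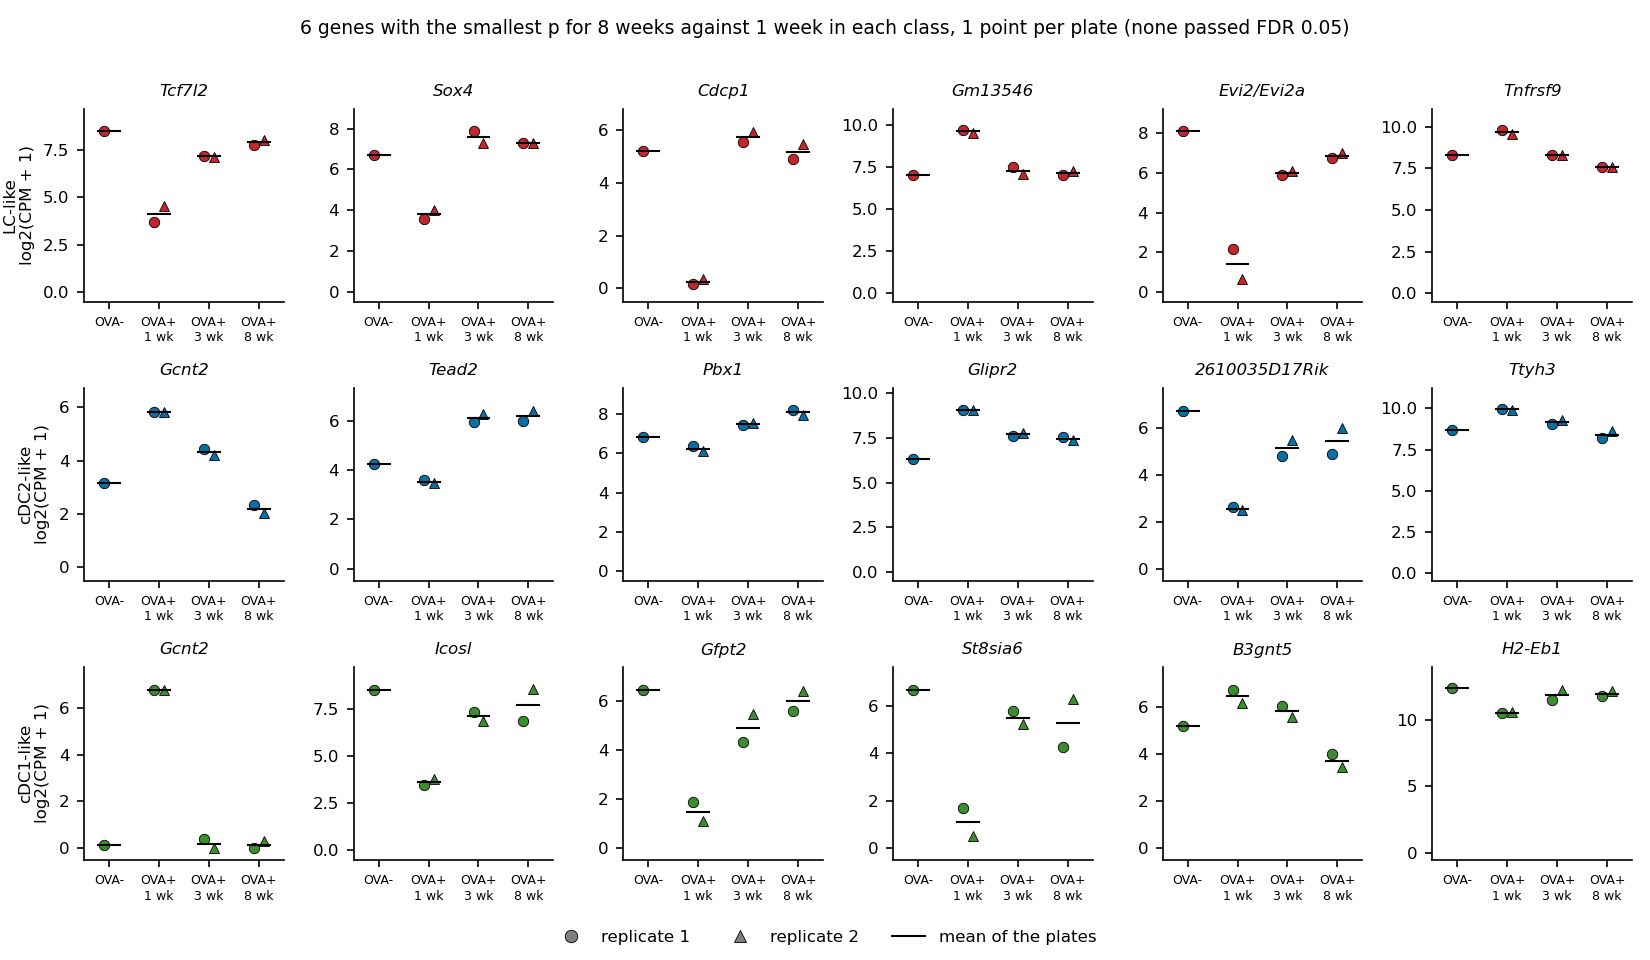
Genes with the 6 smallest p values for 8 weeks against 1 week in each class, as log2(CPM + 1), with 1 point per plate for 1, 3 and 8 weeks and the OVA- plate. In LC-like cells Tcf7l2 averaged 17.2 CPM at 1 week and 239 CPM at 8 weeks, and 0 of the genes passed an FDR of 0.05.

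The interaction test asked whether the difference between 8 weeks and 1 week was itself different in LC-like and cDC2-like cells of the same plates. Cholesterol synthesis had a median log2 difference of -1.17 for the LC-like minus the cDC2-like change (adjusted p = 0.000391), and the type I interferon response one of -0.85 (adjusted p = 0.0178). MHC class II presentation had a median of 1.26 (adjusted p = 0.000495). With an estimated correlation the adjusted p was 0.409 for each of the 3 lists. By edgeR 0 of 19046 genes differed, with 395 at an unadjusted p of 0.05 or less and 20 called by DESeq2, among them Tcf7l2, Clu and H2-Eb1, which are given here after their values were seen. On the plates, the mean log2(CPM + 1) of the cholesterol synthesis list in LC-like cells was 6.17 and 5.89 at 1 week against 4.94 and 5.35 at 8 weeks. In cDC2-like cells it was 4.77 and 4.91 against 4.33 and 5.63, so the 8-week plates lay on both sides of the 1-week plates. As LC-like cells of the 1-week plates came mostly from cluster 3, the interaction compares classes whose makeup also differed.

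**Figure D4:**
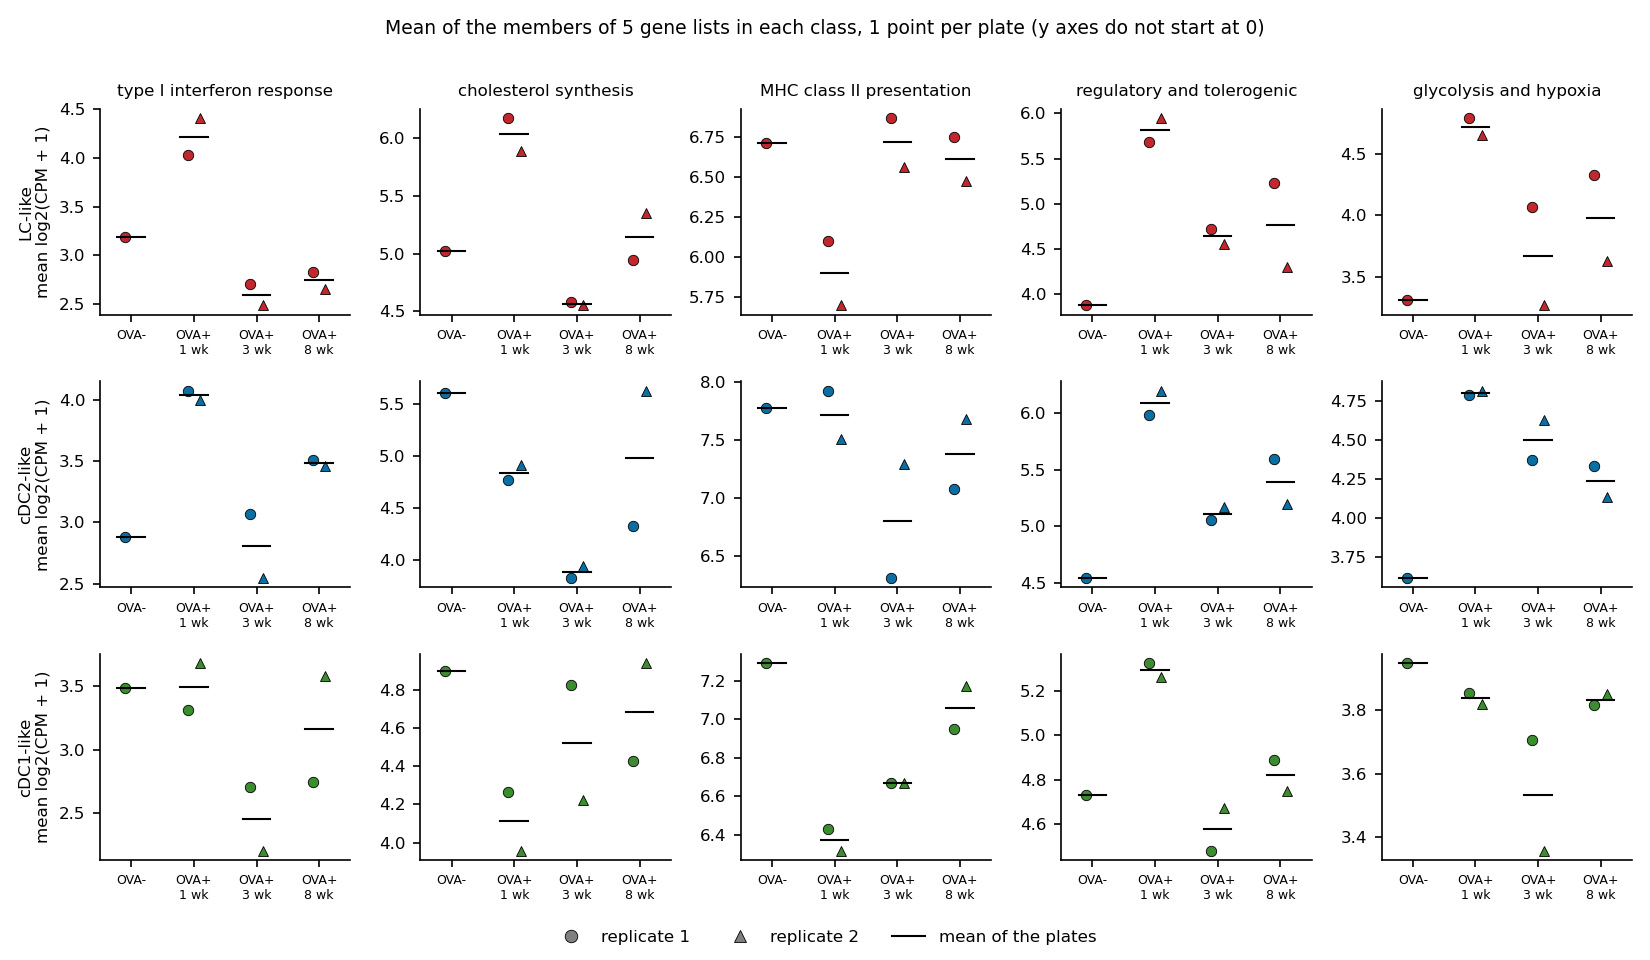
Mean log2(CPM + 1) of the members of 5 gene lists in the 3 classes, with 1 point per plate for 1, 3 and 8 weeks and the OVA- plate, on y axes that do not start at 0. In LC-like cells the type I interferon response list averaged 4.03 and 4.41 on the 1-week plates and between 2.48 and 3.19 on the others.

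The comparison of OVA+ DCs, as the mean of the 3 times, with OVA- DCs asked how the sorted OVA+ and OVA- cells differed. The OVA- group was a single plate, so it was assumed to vary like the OVA+ groups, and OVA status and plate cannot be told apart in it, nor time if T0 was another time. The makeup of the LC-like class differed as well. Cluster 3 held 88.5% and 74.7% of its cells on the 1-week plates, which are among the OVA+ plates, against 4.17% on the OVA- plate. In LC-like cells, Cryaa measured 6.05 CPM on the OVA- plate and 138 ± 63.7 CPM on the OVA+ plates (n = 6), a log2 difference of 4.40 (SE 0.674, FDR 0.635). Rpl39l measured 152 CPM on the OVA- plate and 9.01 ± 7.84 CPM on the OVA+ plates, and the reads shared by Evi2 and Evi2a 277 and 60.5 ± 51.7 CPM. Sptbn2 and Sspo were near 0 at 1 and 3 weeks and measured 101 and 87.8 CPM on the OVA- plate, but the 8-week plates had 55.8 and 44.9 CPM of Sptbn2 and 3.37 and 42.0 CPM of Sspo. The chemokine Cxcl1 measured 34.0 ± 8.53 CPM on the OVA+ plates and 0.11 CPM on the OVA- plate, and Il1rn, the interleukin 1 receptor antagonist, 47.2 ± 24.0 and 0.55 CPM. Ccl5, a chemokine, was highest on the OVA- plate, at 9507 CPM against 3107 ± 2020 CPM, and Nfkb1 lowest, at 322 CPM against 1191 ± 664 CPM.

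Over a class of this differing makeup, the regulatory and tolerogenic list lay higher in OVA+ LC-like cells for 19 of 23 members, with a median of 1.26. Glycolysis and hypoxia lay higher for 15 of 18, with a median of 1.21. Ribosomal protein genes lay lower for 66 of 84 members, with a median of -0.52. Each of these 3 lists had an adjusted p of 0.00130, and an adjusted p of 0.589 with an estimated correlation, and the calls stayed without any 1 of the 6 OVA+ plates, with adjusted p of at most 0.0119, 0.0115 and 0.0252. The OVA- plate, on which all these comparisons rest, could not be left out. The mean log2(CPM + 1) of glycolysis and hypoxia was 3.27 on 3-week replicate 2 and 3.63 on 8-week replicate 2, near the 3.32 of the OVA- plate. On the remaining OVA+ plates it was 4.07 to 4.79. For the regulatory and ribosomal lists all 6 OVA+ plates lay on the same side of the OVA- plate. In the cells of cluster 2 alone only the regulatory call stayed (adjusted p = 0.0199), with 0.0896 for glycolysis and 0.170 for the ribosomal list. The edgeR test called 0 genes, with 935 of 14402 at an unadjusted p of 0.05 or less, while DESeq2 called 155 higher and 27 lower and limma called 0. Without the filter on low counts edgeR called 79 higher and 108 lower, the reverse balance of DESeq2. When adjusted over the list alone, 5 member genes were higher and 5 lower.

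In cDC2-like cells, the genes of the T cell ligands Cd80, Pdcd1lg2 and Cd274 had higher values in OVA+ cells. Cd80 (ENSMUSG00000075122, chromosome 16, 38455561 to 38496335, GRCm38) measured 3.98 CPM on the OVA- plate and 75.5 ± 40.3 CPM on the OVA+ plates (n = 6), a log2 difference of 4.10 (SE 0.528, FDR 0.13). Pdcd1lg2 measured 2.57 and 538 ± 433 CPM, a log2 difference of 7.36 (SE 1.11, FDR 0.137), and Cd274, which encodes the inhibitory ligand PD-L1, 129 and 530 ± 214 CPM, a difference of 1.95 (SE 0.467, FDR 0.343). Ckap4 measured 1.95 and 73.6 ± 24.1 CPM, a log2 difference of 5.18 (SE 0.644, FDR 0.13), and Cryaa 3.74 and 74.3 ± 30.7 CPM. Bnip3, Abhd14b and Zc3h12d measured 0, 0.08 and 0.47 CPM on the OVA- plate and 24.8 ± 7.19, 28.7 ± 10.9 and 54.6 ± 39.3 CPM on the OVA+ plates, but by marker score Zc3h12d turned to a log2 difference of -0.94. Icosl went the other way, with 279 CPM on the OVA- plate and 55.5 ± 67.1 CPM on the OVA+ plates, as did Hmgcs1, an enzyme of cholesterol synthesis, with 260.4 and 104 ± 63.8 CPM, and the heat shock gene Hspa1b, with 1482 and 419 ± 363 CPM. Glycolysis and hypoxia genes lay higher for 15 of 18 members, with a median of 0.74 (adjusted p = 0.00172, and adjusted p = 0.512 with an estimated correlation), and the regulatory and tolerogenic list for 16 of 23, with a median of 0.61 (adjusted p = 0.0155, and adjusted p = 0.512 with an estimated correlation).

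Lower in OVA+ cDC2-like cells lay cholesterol synthesis, for 14 of 17 members with a median of -1.11 (adjusted p = 0.0166, and adjusted p = 0.716 with an estimated correlation), and immediate early and heat shock genes, for 17 of 22 with a median of -0.88 (adjusted p = 0.0302, and adjusted p = 0.763 with an estimated correlation). Ribosomal protein genes lay lower for 64 of 85 members, with a median of -0.48 (adjusted p = 0.00225, and adjusted p = 0.719 with an estimated correlation). The glycolysis and ribosomal calls stayed without any 1 of the 6 OVA+ plates, with adjusted p of at most 0.00477 and 0.0167. The regulatory call ended without 1-week or 3-week replicate 2, up to 0.0634, the cholesterol call without either 1-week plate or 3-week replicate 2, up to 0.0701, and the heat shock call without any OVA+ plate but 8-week replicate 2, up to 0.111. Without both 3-week plates the cholesterol and heat shock calls ended (adjusted p = 0.160 and 0.141). By marker score the regulatory, glycolysis and cholesterol calls ended (0.0543, 0.0923 and 0.676). On the plates, 8-week replicate 2 stood apart from the other OVA+ plates in the cholesterol and heat shock lists. Its mean log2(CPM + 1) of cholesterol synthesis was 5.63, against 5.61 on the OVA- plate and 3.83 to 4.91 on the other OVA+ plates. For heat shock genes the values were 7.13 against 6.95 and 5.40 to 6.25. By edgeR 0 genes passed, with 1516 of 16821 at an unadjusted p of 0.05 or less, while DESeq2 called 306 higher and 66 lower. The balance was the reverse with limma, 8 higher and 139 lower, and with edgeR without its filter, 197 higher and 240 lower. Pdcd1lg2 passed, higher, when either 8-week plate was left out, and 2610528A11Rik, named after its values were seen, passed, lower, without 3-week replicate 2, so the count was 1 in each case. Adjusted over the list alone, 14 member genes were higher and 5 lower.

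In cDC1-like cells, the MHC class II genes H2-Ab1, H2-Eb1, H2-Eb2 and Cd74 had lower values in OVA+ cells, although the list as a whole was not called. H2-Ab1 (ENSMUSG00000073421) measured 1847 CPM there and 573 ± 200 CPM on the OVA+ plates (n = 6), a log2 difference of -1.73 (SE 0.306, FDR 0.996), and H2-Eb1 5404 and 3070 ± 1410 CPM. Lbh, a transcription cofactor, measured 186 and 31.1 ± 33.7 CPM, a log2 difference of -3.21 (SE 0.478, FDR 0.863) that turned to 1.32 by marker score, and Serpinb1b 35.1 and 4.93 ± 6.56 CPM. Pdzk1ip1 and 4930412M03Rik measured 40.4 and 27.7 CPM on the OVA- plate and 1.07 and 0 CPM on the OVA+ plates. Icosl measured 369 CPM on the OVA- plate and 133 ± 136 CPM on the OVA+ plates. The costimulatory ligand Cd86 had higher values in OVA+ cells, 181 ± 111 against 38.4 CPM. Ribosomal protein genes lay lower for 73 of 84 members, with a median of -0.55 (adjusted p = 0.000483, and adjusted p = 0.580 with an estimated correlation), and the call stayed without any 1 of the 6 OVA+ plates, with adjusted p of at most 0.0110. The edgeR test called 0 genes, with 689 of 14877 at an unadjusted p of 0.05 or less, while DESeq2 called 14 higher and 4 lower. Here too limma, with 0 higher and 114 lower, and edgeR without its filter, with 8 higher and 31 lower, had the reverse balance. When adjusted over the list alone, 0 member genes were higher and 6 lower.

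The 3-week plates, with 83 and 131 kept cells, were compared with the plates of the other times as a secondary question, and their sums rest on as few as 15 cells of a class. In cDC1-like cells of 3-week replicate 1, the summed B cell markers reached 6670 CPM, of which Igkc alone made up 6640 CPM. In the cDC1-like cells of the other plates the sums were 0.559 to 141 CPM. Cells bearing CD19 had been depleted before the sort. In LC-like cells, Clu, a chaperone gene, measured 9.41 ± 7.25 CPM at 1 week and 338 ± 115 CPM at 3 weeks, a log2 difference of 5.17 (SE 0.682, FDR 0.182), and Sox4 13.04 and 197 CPM. Zbtb11 and Lats2 measured 47.7 and 115 CPM at 1 week, 0 and 0.255 CPM at 3 weeks and 62.4 and 84.4 CPM at 8 weeks. Rbpms measured 6.94 ± 0.608 CPM at 3 weeks and 147 ± 53.1 CPM at 8 weeks, a log2 difference of 4.39 (SE 0.636, FDR 0.341), and P2ry13, Sord and Sptbn2 were also near 0 at 3 weeks and between 50.02 and 71.5 CPM at 8 weeks. In cDC2-like cells, Rhot2 and Lilr4b measured 96.0 and 52.8 CPM at 1 week and 15.2 and 6.4 CPM at 3 weeks, with an FDR of 0.643 for each. Phf11a and Plpp6 measured 1.83 and 9.82 CPM at 3 weeks and 57.9 and 56.6 CPM at 8 weeks, with an FDR of 0.68 for each, and Zfp85, Tmem268, Susd2 and Lrmp were at or near 0 at 3 weeks. In cDC1-like cells, Pkib measured 201 ± 6.77 CPM at 1 week and 17.1 ± 5.01 CPM at 3 weeks, a log2 difference of -3.56 (SE 0.485, FDR 0.205), Slc4a8 162 and 502 CPM, Gnptab 80.9 and 10.6 CPM and Fkbp4 52.0 and 1.35 CPM. Samd10 measured 6.47 ± 4.79 CPM at 3 weeks and 123 ± 21.2 CPM at 8 weeks, and Lbh 7.18 and 70.2 CPM, with an FDR of 0.695 for each. Lbh turned to a log2 difference of -0.11 by marker score.

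Between 1 and 3 weeks the type I interferon response lay lower, with medians of -2.32 in LC-like, -0.95 in cDC2-like and, with classes by clustering only, -1.06 in cDC1-like cells (adjusted p = 0.00119, 0.00200 and 0.0457, and adjusted p = 0.377, 0.262 and 0.403 with an estimated correlation). The regulatory and tolerogenic list lay lower at 3 weeks for 22 of 23 members in cDC2-like cells, with a median of -0.89 (adjusted p = 0.000228, and adjusted p = 0.262 with an estimated correlation). Cholesterol synthesis lay lower for 15 of 17 members in LC-like cells and 17 of 17 in cDC2-like cells and higher for 11 of 16 in cDC1-like cells, with medians of -1.25, -1.11 and 0.69 (adjusted p = 0.00119, 0.0146 and 0.0168, and adjusted p = 0.377, 0.719 and 0.403 with an estimated correlation). MHC class II presentation lay higher for 12 of 15 members in LC-like cells, lower for 12 of 15 in cDC2-like and higher for 9 of 15 in cDC1-like cells (adjusted p = 0.00186, 0.0198 and 0.0279, and adjusted p = 0.377, 0.719 and 0.403 with an estimated correlation), and whether the classes differed was not tested between these times. The list of TGF-beta response and Langerhans cell maintenance lay lower in cDC2-like cells, with a median of -0.48 (adjusted p = 0.0244, and adjusted p = 0.401 with an estimated correlation). Pattern recognition and uptake receptors lay lower in cDC1-like cells for 13 of 16 members, with a median of -1.66 (adjusted p = 0.00899, and adjusted p = 0.403 with an estimated correlation). Mitochondrially encoded genes lay higher in cDC1-like cells for 10 of 10 members, with a median of 0.66 (adjusted p = 0.00135, and adjusted p = 0.403 with an estimated correlation). Ribosomal protein genes had medians of 0.36, 0.28 and 0.35 in LC-like, cDC2-like and cDC1-like cells (adjusted p = 0.00119, 0.00649 and 0.0113, and adjusted p = 0.749, 0.732 and 0.518 with an estimated correlation), and in LC-like cells the mean of the list was -0.01, of the other sign. From 3 to 8 weeks, mitochondrially encoded genes lay lower in LC-like cells for 11 of 11 members, with a median of -0.66 (adjusted p = 0.00751, and adjusted p = 0.806 with an estimated correlation), and cholesterol synthesis higher in cDC2-like cells for 17 of 17, with a median of 1.36 (adjusted p = 0.00357, and adjusted p = 0.816 with an estimated correlation).

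Of these 18 calls that involve 3 weeks, those of the regulatory and interferon lists in cDC2-like cells and of the mitochondrial list in cDC1-like cells stayed whichever plate was left out, with adjusted p of at most 0.0147, 0.0483 and 0.0297. In LC-like cells, leaving out 3-week replicate 1 ended the calls between 1 and 3 weeks of the interferon list (as did 1-week replicate 2), cholesterol synthesis and MHC class II, up to 0.122, 0.112 and 0.0581. Leaving out 3-week replicate 2 ended those of the ribosomal list, up to 0.342, and, like 8-week replicate 2, of the mitochondrial list, up to 0.32. In cDC2-like cells the MHC class II call ended without replicate 1 of any OVA+ time or 8-week replicate 2, up to 0.655. The cholesterol and TGF-beta calls between 1 and 3 weeks ended without any of the 1-week or 3-week plates, up to 0.162 and 0.295, the ribosomal call without 1-week replicate 1 or 3-week replicate 2, up to 0.739, and the cholesterol call between 3 and 8 weeks without 3-week replicate 1 or 8-week replicate 2, up to 0.661. For cDC1-like cells the interferon call ended without any of the 1-week or 3-week plates, up to 0.186, and the MHC class II call without any OVA+ plate but 1-week replicate 2, up to 0.196. The cholesterol call ended without 3-week replicate 1 or 1-week replicate 2, up to 0.190, the pattern recognition call without either 3-week plate, up to 0.0702, and the ribosomal call without 1-week replicate 1 or 3-week replicate 2, up to 0.750. With classes by marker score 0 of the 6 cDC1-like calls between 1 and 3 weeks stayed. The interferon list went the other way (adjusted p = 0.754), and cholesterol synthesis was called lower (0.0345). MHC class II, pattern recognition, ribosomal and mitochondrial lists had 0.305, 0.398, 0.174 and 0.195. The same classes ended the calls between 1 and 3 weeks of MHC class II and ribosomal lists in LC-like cells (0.217 for each) and of the interferon, MHC class II and TGF-beta lists in cDC2-like cells (0.559, 0.838 and 0.174). In the cells of cluster 2 alone 0 of the 5 LC-like calls stayed, with 0.921 for interferon, 0.230 for MHC class II, 0.0601 for cholesterol, 0.767 for ribosomal and 0.311 for mitochondrial genes. Genes of at least 20 CPM ended the interferon and mitochondrial calls in LC-like cells (0.126 and 0.192) and the TGF-beta call in cDC2-like cells (0.721). By edgeR 0 genes passed between 1 and 3 weeks, with 1129, 939 and 945 genes at an unadjusted p of 0.05 or less in LC-like, cDC2-like and cDC1-like cells, 347, 134 and 224 by DESeq2 and 0 by limma. From 3 to 8 weeks 0 genes passed, with 1005, 1164 and 858 at an unadjusted p of 0.05 or less, 283, 175 and 149 by DESeq2 and 0 by limma. Without 3-week replicate 1, which held the Igkc reads, edgeR called 75 and 85 genes in cDC1-like cells, between 1 and 3 and between 3 and 8 weeks. Adjusted over the list alone, member genes higher and lower between 1 and 3 weeks numbered 6 and 4 in LC-like, 0 and 6 in cDC2-like and 7 and 6 in cDC1-like cells, and from 3 to 8 weeks 5 and 0, 4 and 2, and 3 and 0.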

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

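The gene lists and the interaction test were fixed before the data were examined, whereas the kinds of cells set aside were defined from the data. Between LC-like and cDC2-like cells the change from 1 to 8 weeks differed by the interaction test for 3 lists, as the median of the LC-like minus the cDC2-like log2 difference. It was -0.85 for the type I interferon response, 1.26 for MHC class II presentation and -1.17 for cholesterol synthesis, with adjusted p of 0.0178, 0.000495 and 0.000391, and 0.409 for each with an estimated correlation. Both 1-week plates differed from the others in the clusters that made up their LC-like cells, so these differences and that of cluster makeup stand together.

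Among cells outside every comparison of classes by clustering, the share of low-depth cells had a 95% exact interval wholly above the share of the OVA- plate, 16.1% (12.3 to 20.6%), on 3 plates. It was 29.0% (21.4 to 37.6%) on 3-week replicate 1, 28.9% (19.5 to 39.9%) on 3-week replicate 2 and 29.2% (23.3 to 35.7%) on 8-week replicate 1, and the interval of 8-week replicate 2, with 18.3%, included 16.1%. Macrophage-like cells made up 3.65% (1.59 to 7.07%, 8 cells) of kept cells on 8-week replicate 1 against 1.24% (0.338 to 3.14%, 4 cells) on the OVA- plate, so these intervals overlap. On 8-week replicate 2 the share was 0.345%. Such intervals do not measure the spread between plates. With many plates and kinds of cells compared, some such differences arise by chance, and no adjustment was made.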

How the results depend on the processing

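Chosen after the data had been seen were classes at resolution 0.5, genes with a mean of at least 20 CPM, limma-trend on the mean over cells of log2(CPM + 1), leaving out both 3-week plates, LC-like cells of cluster 2 alone, and camera under each setting. The count of 0 genes by edgeR kept its value in every class comparison without TMM, with cells of at least 1000 genes, with genes of at least 20 CPM and by limma on mean logs. No paired analysis was possible because the labels carry no replicate numbers, the numbers here only telling the plates of a group apart. The number of genes called depended on the tool. For 8 weeks against 1 week, 3 weeks against 1 week, 8 weeks against 3 weeks and OVA+ against OVA-, DESeq2 called 199, 347, 283 and 182 genes in LC-like, 167, 134, 175 and 372 in cDC2-like and 81, 224, 149 and 18 in cDC1-like cells, and 20 for the interaction. Without a filter on low counts, edgeR called 196, 221, 137 and 187 genes, 204, 146, 219 and 437, and 76, 130, 50 and 39 in the same order, and 41 for the interaction. The limma fit on the mean CPM over cells called 147 and 114 genes for OVA+ against OVA- in cDC2-like and cDC1-like cells and 0 elsewhere. Classes by marker score gave 2 genes (Ccnd2 and Gm13546) for 8 weeks and for 3 weeks against 1 week and 1 (Sptbn2) for OVA+ against OVA- in LC-like cells. In cDC1-like cells they gave 2 (Ccnd2 and Trmt2a) for 3 weeks against 1 week and 3 (with 9330175E14Rik) for 8 weeks against 3 weeks, and the interaction 1 (Atf7ip2). Cluster 2 alone gave 21 genes for 8 weeks and 5 (Evi2/Evi2a, Irf8, Map2k7, Mfge8 and Serpinb1a) for 3 weeks against 1 week. Resolution 0.5 gave 1 gene (Clu) for 3 weeks against 1 week in LC-like cells, and without both 3-week plates 1 gene (Gcnt2) was called for 8 weeks against 1 week in cDC1-like cells. Genes named in these counts outside the rule were chosen after their values were seen, and the cause of these differences was not tested.

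Leaving out 1 plate at a time gave 0 genes except in 5 results. The count ranged from 0 to 1 for OVA+ against OVA- in cDC2-like cells and for the interaction (Pdcd1lg2, without 8-week replicate 1), and from 0 to 3 for 8 weeks against 1 week in cDC1-like cells. There it ranged from 0 to 75 for 3 weeks against 1 week, with 1 gene (Flrt3) without either 8-week plate, and from 0 to 85 for 8 weeks against 3 weeks, the highest counts without 3-week replicate 1. A plate left out of a group of 2 leaves a lone plate that is assumed to vary like the others, and the OVA- comparisons have no value without the OVA- plate. Of the 37 list calls, 0 held with an estimated correlation and 7 with fry. Camera gave 38 calls without TMM, 48 without a filter, 37 with cells of at least 1000 genes, 38 at resolution 0.5 and 40 with genes of at least 20 CPM, of which 37, 37, 37, 37 and 31 were among the 37. Classes by marker score gave 36, 18 of them shared and 1 in the opposite direction. Without 1 plate there were 26 to 43 calls, cluster 2 alone kept 2 of 14, and without both 3-week plates 16 of 19 stayed.

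Some lists and genes changed direction. With LC-like cells of cluster 2 alone, the cytosolic ribosomal proteins list for 8 weeks against 1 week turned (adjusted p = 0.539). By marker score, cholesterol synthesis in cDC1-like cells turned for 8 weeks and for 3 weeks against 1 week (adjusted p = 0.281 and 0.0345), as did the type I interferon response for 3 weeks against 1 week (adjusted p = 0.754). By the same classes the log2 difference turned to -0.00273 for Pvr in LC-like, -0.94 for Zc3h12d and -0.66 for H2-DMb2 in cDC2-like and 1.32 for Lbh in cDC1-like cells, OVA+ against OVA-. It turned to 0.19 for Tgfbi (8 weeks against 1 week) and -0.11 for Lbh (8 weeks against 3 weeks) in cDC1-like cells. On mean logs it was 0.0412 for Cxcl10 in LC-like and 0.0903 for Clec4n in cDC2-like cells, OVA+ against OVA-. Why these turned was not tested. Of 2567 values of named genes under the alternatives, 268 passed the FDR and 8 had the opposite sign. Of the 268, 116 came from DESeq2 and 125 from edgeR without its filter. The genes had been chosen by their p values on these same plates, so a kept sign is no independent support. Shares of classes moved beyond their interval in 10 of 63 values, all at resolution 2. Of these, 7 were cDC2-like shares, with a fall from 69 to 9 cells on 8-week replicate 2 and from 75 to 12 on the OVA- plate. The other 3 were cDC1-like shares, which fell from 24.5% to 19.7% on 1-week replicate 2, from 18.1% to 8.43% on 3-week replicate 2 and from 20.1% to 11.9% on 8-week replicate 1, and 22 to 71 cells per plate were unnamed. No test between groups was made with these classes. Median genes per cell fell in 21 of 21 when cells were thinned to 20000 reads. Taking reads away can only lower the genes seen in a cell, so this count tests nothing.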

Other observations

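The count of cluster 2 cells that lie nearer to the mean of cluster 3 was chosen after the values within cluster 2 had been seen. The comparison with draws from all reads was not part of the rule fixed beforehand for reads per cell. The other tests were fixed before their results. Immediate early and heat shock genes separated the plates in another way than time. Their mean log2(CPM + 1) in LC-like cells was 6.59 on 8-week replicate 2 and 6.19 on the OVA- plate, and between 4.52 and 5.44 on the other plates. In cDC2-like cells it was 7.13 and 6.95 on these plates against 5.40 to 6.25 elsewhere, and in cDC1-like cells 6.53 and 6.11 against 4.47 to 5.92. Inflammatory cytokines and chemokines in LC-like cells averaged 4.22 and 4.64 on the 1-week plates and 4.04 on 8-week replicate 1, against 2.5 to 3.13 on the others, and the list was not called between 8 weeks and 1 week.

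Genes detected per LC-like cell, after thinning every cell to 20000 reads, had medians of 2451 and 2108 on the 1-week plates, 2104 and 1623 on the 3-week plates, 1854 and 1771 on the 8-week plates and 1419 on the OVA- plate. In cDC2-like cells the OVA- plate was also lowest, at 1945 against 2203 to 2671. In cDC1-like cells it had 2130.5, within the 1983 to 2308 of the other plates. Whether this bears on the differences between OVA+ and OVA- cells was not tested. Mast-like cells, set aside, made up between 0.606% and 3.45% of the kept cells of a plate.

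In the distances between plates (median absolute log2 difference over genes), 8-week replicate 2 was nearer to the OVA- plate than 8-week replicate 1 was. For RNA or cells of another type, the largest difference between the 8-week plates in summed markers was 299.5 CPM, for B cells in LC-like cells. This was far under the 10000 CPM set beforehand. No marker sum on any plate reached that bound, so the result argues only against a large admixture, and a smaller one stays open. Igkc measured 519, 304 and 80.0 CPM on 8-week replicate 1 in LC-like, cDC2-like and cDC1-like cells. On 8-week replicate 2 it measured 48.0, 0.435 and 0.177 CPM, and on the OVA- plate 14.1, 0.791 and 2.08 CPM. A mislabelled plate that holds OVA- cells stays open. The distance between 8-week replicate 2 and the OVA- plate exceeded those of both the 1-week and the 3-week pairs in 2 of 3 classes, at 1.15 in LC-like and 0.883 in cDC2-like cells but 0.747 in cDC1-like cells, where the 3-week pair lay 0.769 apart. The 8-week pair lay 1.07, 0.84 and 0.776 apart in the same order, so 8-week replicate 2 was nearer to its partner in 2 classes. These differences were close to the SD over draws of 0.0352 to 0.0611 and cannot decide on a wrong label. Class makeup, counted after the data had been seen, set 8-week replicate 2 with the OVA- plate. At resolution 2, 1 cluster held 41 of 69 and 49 of 86 cDC1-like cells there, against 6 of 44 on 8-week replicate 1. Another held 43 of 69, 41 of 75 and 14 of 56 cDC2-like cells in that order. Cluster 3 held 4.55%, 4.17% and 23.3% of LC-like cells. At 20000 reads per cell, 8-week replicate 2 was nearer to the OVA- plate in 82, 79 and 92 of 100 draws in LC-like, cDC2-like and cDC1-like cells. These counts met the outcome set beforehand for a difference in reads per cell. With all reads the counts were 84, 81 and 98, so thinning changed them little and the pattern in the distances was uncertain before it. A difference in reads per cell could therefore not be decided either, and no biological explanation was tested.

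LC-like cells of the 1-week plates fell mostly in another cluster than those of the other plates. Of LC-like cells with at least 20000 reads, thinned to that depth, 96.1% and 92.8% on the 1-week plates lay nearer to the mean of cluster 3. On any other plate at most 31.8% did. This cannot decide on a difference in reads per cell, since 92 and 74 of the 194 cells of cluster 3 came from the 1-week plates. Any plate difference would pull their cells towards its mean. Median reads per LC-like cell were 94416 and 72922 on the 1-week plates and 135813 and 125498 at 3 weeks. At 8 weeks they were 72426 and 73907.5, and on the OVA- plate 73479, so these plate medians did not run with the share of cluster 3. The 2 clusters did differ in depth. Reads per cell, relative to the median of the plate's kept cells, had a median of 1.16 in cluster 3 and 0.729 in cluster 2. As different plates filled the clusters, these values cannot tell depth from plate. A change in the mix of 2 kinds of LC-like cells, each of them unchanged, stays open. Within cluster 2, 99.7% (95% interval 82.4 to 127.6%) of the difference between 8 weeks and 1 week remained over 492 genes. This passed the bound set beforehand as going against such a change, but the cluster of the 1-week cells is in doubt. At 20000 reads, 24 of the 35 thinned cluster 2 cells of the 1-week plates (68.6%) lay nearer to the mean of cluster 3, against 0 of 114 on the 8-week plates. As that mean rests mostly on 1-week cells, this count cannot tell another kind of cell from a plate difference, so the question is not decided. A change of the cells with time is also open, and time cannot be told apart from plate.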
